A study of Populus trichocarpa with 2 samples.

How the data were processed

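Nuclei were isolated from root fragments, stained and sorted, and libraries were prepared with the 10x Genomics Chromium 3′ kit, per the labels' protocols. In that assay the RNA of each nucleus is tagged in a droplet with a bead barcode, and reads are counted at the 3′ ends of transcripts. The plants had been raised under a 16 h light and 8 h dark cycle at 18 and 14 °C before they were moved to rhizotrons in a greenhouse tunnel, per the labels' protocols. Cell Ranger 7.1.0 is named in the submitters' processing notes. The genome build, the annotation and the rule by which barcodes were retained are not given in the sources used here. The ending of the locus tags, v4, is the only sign of the annotation version in the deposited lists.

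The files analysed hold text and no measurement. As deposited, the barcode list of each library has 1 line per barcode with the suffix common to a single run, and the feature list has a gene identifier, a gene name and a feature type per line. Matrices of counts were not analysed here. Tests of gene expression, clustering, cell type naming and doublet detection were therefore not run, and the depth per library is unknown. The number of listed barcodes depends on the retention rule, which is a property of the processing as well as of the sample.

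Both libraries were assigned to 1 group, root, from their titles, and the replicate numbers were taken from the same titles. The tests, gene families and alternatives were fixed before the data were examined, except where stated. The expected number of shared barcodes was the product of both list lengths divided by the size of the barcode list, set at 7000000 from general knowledge of the kit, and sharing was tested with an exact hypergeometric test. Alternatives were 3500000 and all possible 16-base sequences. Pairs of barcodes 1 base apart were counted within and between libraries, without the barcodes shared by both, and an exact binomial test was planned against the share of all pairs that lie within a library. Alternatives were a distance of 2 bases, each library left out and shared barcodes kept. Pairs have barcodes in common and are not fully independent, so the intervals are approximate. Base composition was described per position, and the alternative left out shared barcodes. A permutation of barcodes between libraries (100000 resamples) had been planned; it treats barcodes as replicates of 2 single libraries, so its p-value is not reported. Poisson and binomial intervals are at the 95% level and cover counting error only.

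Features were grouped by the prefix of the identifier into nuclear, chloroplast and mitochondrial genes, and organelle genes were grouped by the start of their symbol. The rule for named genes was to name every sieve element occlusion gene, with the first members of each other family as examples. It named none, because the nuclear identifiers carry no gene names and 0 of them matched the RefSeq gene table of assembly P.trichocarpa_v4.1. The organelle genes named in the report were therefore chosen outside that rule, after the lists had been seen. The tags of the chloroplast genes matched that table, which was used for names and gene types only. A match of the mitochondrial entries to the table is not reported here. Tandem arrangement and similarity of 3′ ends of family members were planned and were not run for the same reason and because no genome sequence was used here.

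Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used. The counting of barcodes was tested on simulated lists, in which 60 of 60 planted pairs 1 base apart and 200 of 200 planted shared barcodes were recovered. The simulated barcodes were random sequences without the structure of the kit's list. Counts of pairs 2 bases apart and of partner pairs were not tested in this way.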

Results

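Single-nucleus RNA libraries were made from pioneer roots of black cottonwood (Populus trichocarpa), a poplar tree whose genome serves as a reference for woody plants. Pioneer roots are the long, fast-growing roots that extend the root system, and the sampled fragments covered the stages at which the primary vascular tissue forms. The series title places the interest in the phloem, the tissue that carries sugars, and in the protein structures of its sieve elements, the conducting cells of that tissue. Both libraries came from untreated wild-type roots and formed a single group, root, with 2 replicates. The labels therefore set no treatment, genotype or tissue against another, and they do not say whether the replicates came from separate plants. The values analysed here were the barcode list and the gene list of each library. Counts per nucleus and gene were not analysed here, so no expression level, cell cluster or share of a cell type is given, and the sequencing depth of the libraries is unknown. Levels of sieve element, companion cell or xylem genes would need those counts.

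The only measure of yield was the number of barcodes listed per library. It is not a count of nuclei in either library, because the rule by which barcodes were retained is not given. A barcode is the 16-base tag carried by a gel bead, and each listed barcode stands for a droplet retained in the deposited table. Replicate 1 listed 21699 barcodes and replicate 2 listed 16119, which gave a mean of 18909 ± 3946 (SD, n = 2). Replicate 1 thus held 1.35 times as many barcodes as replicate 2. Per the labels' protocols, approximately 20000 nuclei were combined with reverse transcription reagents for a library. The listed barcodes amounted to 108% of that number in replicate 1, an excess of 1699, and to 80.6% in replicate 2. With 1 group of 2 libraries, the difference between replicates was not tested. All 37818 listed barcodes had 16 bases, and no barcode was repeated within a library.

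The genes that could receive a count were the same in both libraries. The lists held 32215 features, identical in identity, name and order, and all were of 1 type, gene expression. Nuclear genes made up 32064 of the features, each given by a POPTR locus tag with the version ending v4. By the chromosome number in the tag, 31875 of these lay on chromosomes 1 to 19, and 189 carried tags outside the numbered chromosomes. Chromosome 1 had 3788 listed genes and chromosome 19 had 1105, with a median of 1369 per chromosome. Chromosome 6 followed chromosome 1 with 2321 genes, and chromosome 2 had 2142. Of the nuclear features, 0 had a gene name other than the locus tag. Sieve element occlusion genes, which encode the filament proteins of sieve elements, could therefore not be picked out by name. The same held for sucrose transporters, callose synthases, cellulose synthases and the other families fixed beforehand, so that 0 of 15 families searched by name had a member.

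**Figure D1:**
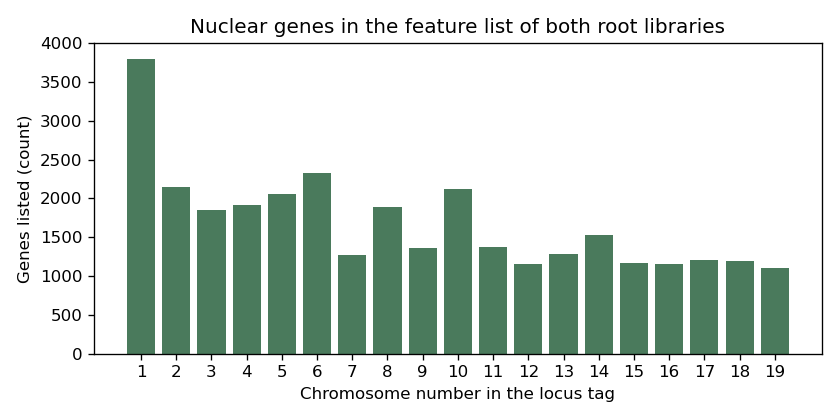
Bars show the number of nuclear genes in the feature list (y axis, count of genes) for each chromosome number in the locus tag (x axis, chromosomes 1 to 19); the list was identical in both root libraries. Chromosome 1 holds 3788 genes and chromosome 19 holds 1105.

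Genes of the organelles made up 151 features, 0.469% of the list. They are the named part of the list, and their transcripts come from outside the nucleus. The chloroplast contributed 100 entries, of which 84 carried 75 distinct gene names and 16 carried none. Photosystem II, which splits water in photosynthesis, had 15 entries, among them psbA, psbB and psbD, and photosystem I had 5, among them psaA and psaB. The chloroplast NADH dehydrogenase complex had 12 entries with 11 names, among them ndhB and ndhF. ATP synthase had 6 entries, as did the cytochrome complex encoded by pet genes. The chloroplast RNA polymerase had 4 entries. Ribosomal proteins formed the largest chloroplast group, with 26 entries and 19 names. The large subunit of Rubisco, the carbon-fixing enzyme, had 1 entry, rbcL.

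The mitochondrion contributed 51 entries, of which 33 carried 32 distinct names and 18 carried none. NADH dehydrogenase, the first complex of the respiratory chain, had 9 entries, among them nad4, nad7 and nad9. Mitochondrial ribosomal proteins had 8 entries, ATP synthase 5 and cytochrome c maturation 4. Cytochrome oxidase, the terminal enzyme of respiration, had 3 entries, namely cox1, cox2 and cox3. Cytochrome b (cob), succinate dehydrogenase (sdh4) and the maturase matR had 1 entry each. The names rpl2, rps12, rps14, rps3, rps4 and rps7 occurred in both organelles and were told apart by the prefix of the entry.

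Several chloroplast gene names were listed more than once, and the rule by which reads shared by their entries were counted is not given in the sources used here. The names ndhB, rpl2, rpl23, rps19, rps7 and ycf2 each had 2 entries, and rps12, whose transcript is joined from separate pieces, had 4. In the mitochondrion, nad2 had 2 entries. Whether the entries of 1 name have reads in common was not tested. With an ending of p and a digit removed where present, the 100 chloroplast entries carried 98 distinct locus tags, so some entries shared a tag. All 100 matched a locus tag of the RefSeq annotation of assembly P.trichocarpa_v4.1, and the 84 named entries carried the same symbols there. That annotation holds 98 protein-coding chloroplast genes, all of which were listed. It also holds 37 transfer RNA and 8 ribosomal RNA genes of the chloroplast, of which 0 were listed. A share of chloroplast reads computed over this list would thus cover protein-coding genes alone.

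Whether the libraries were independent was examined through the barcodes they had in common. The libraries shared 92 barcodes, 0.424% of replicate 1 and 0.571% of replicate 2, with a 95% Poisson interval of 74.2 to 113 that covers counting error only. Independent draws from a barcode list of 7000000, the size assumed beforehand, would share 50.0, so the observed number was 1.84 times that expected (exact hypergeometric test, one-sided, p = 5.9e-08). The ratio depended on the assumed size of the list. Draws from 3500000 barcodes would share 99.9, and the observed number was then 0.921 times that expected (exact hypergeometric test, one-sided, p = 0.80).

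Barcodes that differ by 1 base can arise when a sequencing error turns 1 droplet into 2 listed ones. Among 361844772 pairs within libraries and 346295389 pairs between them, 0 pairs differed by 1 base. The pairs between libraries share the barcode list but not the droplets and served as the control. With 0 pairs between libraries as well, the comparison planned at this distance could not be made. The 0 within libraries therefore says nothing on split droplets. At 2 bases, 3313 pairs were found within libraries and 3097 between them. Random sequences would give 7.91 pairs in all at 1 base and 178 at 2 bases, so they are no usable reference for these barcodes. The rate within libraries was 1.02 times that between them (95% exact interval 0.975 to 1.08, exact binomial test, two-sided, p = 0.35), which was not distinguishable from equal rates. Pairs between libraries, which share no droplets, were almost as many, so a few split droplets would not be seen at this distance.

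The base composition of the barcodes was described for each library. The mean G and C content of a barcode was 49.7% ± 8.68 (SD over barcodes) in replicate 1 and 49.8% ± 8.73 in replicate 2. Over the 16 positions, the share of a base lay between 22.6% and 29.0% in either library. The widest gap was at position 6, counted from the start of the barcode, where G made up 22.9% in replicate 1 and 24.5% in replicate 2, a difference of 1.67 percentage points. With 1 library on each side there is no spread between libraries to hold this gap against, so no difference is called.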

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

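The number of shared barcodes changed sides with the assumed list size: the ratio of observed to expected was 1.84 with 7000000 barcodes and 0.921 with 3500000. Which of these list sizes holds was not settled, and both expectations assume even draws. The partner pairs described below argue against even draws from 7000000 barcodes made of such pairs. They also argue against use of a single partner set of 3500000. All possible 16-base sequences would share 0.0814 barcodes, so any sharing gives an excess there and that setting is no check. The count of close pairs within libraries was 0 at a distance of 1 base, also with shared barcodes kept, and 3313 at 2 bases, at 1.02 times the rate between libraries; leaving out either library from a count of 0 can give no other value and is no check. The gap in base composition was 1.67 percentage points without the shared barcodes, which are too few to move it and so do not check its stability. Leaving out 1 of 2 libraries gives the other's number of barcodes, 16119 or 21699, and does not test the stability of the yield. The alternatives for gene families, tandem copies and 3′ ends were not run, because the nuclear tags could not be paired with names. No paired analysis was possible because the design has 1 group. Depth could not be assessed, and with 2 libraries the spread of the yield rests on a single difference.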

Other observations

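The tests in this part were chosen after the number of shared barcodes was known. Only the prediction on use of a single partner set of the list, explained below, was written before its result was seen. The other predictions were written afterwards.

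The 92 shared barcodes exceeded the 50.0 expected from 7000000, and the structure of the barcodes themselves bears on why. Of 6482 pairs of barcodes 2 bases apart over both libraries, shared barcodes included, 38 differed at positions 8 and 9. In all 38 both bases were complements (partner pairs). Each of the 42 other combinations of positions that occurred had 120 to 187 pairs. How many neighbours the list allows at each combination is not known, so the lower number at positions 8 and 9 is by itself no sign of depletion. Even draws from 7000000 barcodes made of partner pairs would give 102 such pairs, and the upper 95% Poisson limit of those seen was 52.2. This argues against even draws, and so against mixing of libraries on top of even draws as the whole source of the excess. Use of a single partner set of the list is argued against too. It would share 99.9 barcodes, near the 92 seen, but it allows almost no partner pairs and the lower limit was 26.9. The prediction written beforehand was under 25.5 partner pairs, and the 38 seen went against it. A candidate explanation is that barcodes were drawn unequally from 2 partner sets of 3500000 each. With the imbalance taken from the 20 partner pairs within libraries alone, 80.8 shared barcodes and 19.1 partner pairs between libraries were predicted. Found were 92 (95% Poisson interval 74.2 to 113) and 18 (10.7 to 28.4), in a test chosen after both numbers were known. For any imbalance the predictions add up to 99.9, the number set by 3500000 barcodes, so their match adds little support. At position 8, A, C, G and T made up 25.5%, 24.9%, 24.6% and 25.0% of barcodes in replicate 1. In replicate 2 the shares were 24.9%, 25.0%, 25.2% and 24.9%. Complementary bases were thus near equal there, which argues against an imbalance between partner sets told apart by that base. Partner sets divided in another way were not tested. Transfer of a few barcodes between libraries remains possible within these intervals, the partner sets and their size rest on general knowledge of the kit, and no biological explanation was tested.

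Replicate 1 listed 1699 more barcodes than the approximately 20000 nuclei combined with reagents, although some nuclei are usually lost in droplet capture. One hypothesis was that nuclei were listed 2 times, under both partner forms of a bead's barcode. Replicate 1 held 10 such pairs (95% Poisson interval 4.80 to 18.4), far below 1699, and over both libraries 20 pairs lay within a library where 19.4 of all 38 were expected from the share of barcode pairs that lie within a library (exact binomial test, two-sided, p = 0.87). Droplets without an intact nucleus among the retained barcodes, and a true number of nuclei above the approximate one, remain open, since both need counts per barcode or a measured input. A biological difference between the roots of the replicates was not tested.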
